A study of Mus musculus with 6 samples.

How the data were processed

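RNA from primary hepatocytes of male C57Bl/6J mice was measured on 6 single-colour Illumina mouse BeadChip arrays, 2 in each of 3 groups: untreated cells, cells given 2 ng/mL murine tumour necrosis factor alpha (TNFα) for 2 hours, and cells given the same dose for 2 days. Per the labels' protocols, all cells were kept on collagen in medium with 5% fetal calf serum, 50 nM dexamethasone and 1 nM insulin, and biotin-labelled cRNA was hybridised. Each array took its group and replicate number from its title. The labels do not say whether the 2 replicates of a group came from separate animals or cultures, so p-values measure only the spread between these arrays, which may be technical. The labels also do not say how long the untreated cells had been in culture when they were harvested.

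The deposited table holds 1 intensity per probe and array, on a linear scale, for 45281 probes. The values of the 6 deposited intensity columns shared 1 distribution, as after quantile normalization, a step that no label names: every column had the same lowest value (96.54) and highest value (47615.3), and the sorted columns differed by at most 0.332% at any rank. Array medians lay between 143.16 and 143.22. With no value below 96.54, the deposited intensities still held their background, so fold changes of dim probes are understated, and the highest intensities may be compressed. The software used for scanning, summarising and normalizing is not given in the sources used here. No detection p-values were used here.

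Probes were named through the platform's probe table, in which 34885 probes had exactly 1 gene symbol, 18 had several, and 10378 were not listed. Symbols were updated through the entrez identifier for 34807 probes with a RefSeq gene table of assembly GRCm38.p6, used for names alone, since the authors' build is not given in the sources used here. The deposited intensities were converted to log2 without further scaling. A probe passed when at least 2 arrays exceeded that array's 50th percentile, which 26272 probes did, 21425 of them with 1 gene symbol. Each gene was represented by its probe with the highest mean, which gave 13438 genes, of which 5290 had over 1 passing probe. A linear model with a mean per group was fitted to all 6 arrays with limma 3.58.1 in R 4.3.3, with empirical Bayes moderation of the variances. The residual degrees of freedom were 3 and the prior degrees of freedom 21.22. The spread behind each gene's p-value was therefore mostly that shared over all genes, not the gene's own. The 3 contrasts were 2 hours against untreated, 2 days against untreated, and 2 days against 2 hours. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. Precision is limited by the number of arrays.

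Before the data were examined, 24 lists of gene groups and 6 lists of cell type markers were fixed, as were the tests, the alternatives and the rule for naming genes. That rule took the 10 genes with the largest rise and the 10 with the largest fall against untreated cells, and 5 in each direction between the times, among called genes whose arrays did not overlap between the groups. Symbols that are clone or locus names were passed over. Up to 4 called members of each list with the largest change were added. Each list was tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the 30 lists, with the correlation estimated from the data and fry as alternatives. Counts adjusted over the list alone are given beside those over all genes. With an estimated correlation, camera has only the 3 residual degrees of freedom.

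The fit was tested on simulated data of the 2 hour comparison, with 13438 genes of which 200 were changed, in 10 runs. It recovered 90.5% of genes changed by 0.5 on the log2 scale and 100% of those changed by 1, with 4.8% false among the calls. A shift of 0.5 in 1 list was recovered in 20 of 20 runs, with 0 false calls in 580 tests of other lists. Noise was drawn as normal with the SDs of the fit itself, so the model's assumptions held by construction. The runs therefore check the procedure and not the error rate in these arrays. Genes were simulated as independent, so these runs do not test lists whose members vary together. The correlation estimated from the data was 0.324 for the urea cycle and amino acid catabolism genes. Because both comparisons against untreated cells use the same 2 arrays, their agreement was set beside 100 simulations of unchanged groups.

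The alternatives were median centring, cyclic loess, repeated quantile normalization, an offset of 16 before log2, no filter, a filter at the 70th percentile, the mean of a gene's probes, every probe on its own, trended and robust variances, a fit of the compared groups alone, a replicate block, other thresholds, and leaving out each array. A normexp background correction with an offset of 16 was added after the intensities were seen not to be background subtracted. Members of lists without a passing probe were not analysed here. Probes of similar paralogs, such as Cyp2b10 and Cyp2b23, Guca2a and Guca2b, or genes of the H2 locus, may share signal.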

Results

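The arrays measured the response of cultured mouse hepatocytes, the main metabolic and secretory cells of the liver, to TNFα, an inflammatory cytokine, after a short and a long exposure. Each of the 3 groups held 2 arrays. Over the 13438 genes tested, arrays of the same group correlated at 0.995 to 0.996, and arrays of different groups at 0.982 to 0.991. The first principal component, with 55.7% of the variance, separated the 2 day arrays from the other 4. The second, with 22.5%, separated the 2 hour arrays from the untreated ones. Intensities are given as mean ± SD (n = 2), and changes as log2 fold changes with the standard error (SE) and adjusted p of the limma fit.

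The first comparison asked which genes responded within 2 hours. Cxcl1, a chemokine that attracts neutrophils, rose from an intensity of 544 ± 42.6 to 8579 ± 48.8 (n = 2 each), a 15.8-fold change (log2 3.98, SE 0.10, adjusted p = 3.27e-19 by limma). Ccl2, a chemokine that attracts monocytes, rose 12.5-fold, and the leukocyte adhesion molecules Icam1 and Vcam1 rose 11.8-fold and 10.2-fold. Tlr2, a receptor for bacterial lipopeptides, rose 7.12-fold and Stx11, a syntaxin, 6.95-fold. The transcription factor Irf1 rose 6.87-fold, Tnfaip3, a feedback inhibitor of NF-κB signalling, 6.84-fold, Tnfaip2 6.74-fold and the chemokine Cxcl2 6.62-fold. After background correction with normexp the folds of dimmer genes were larger, at 20.5 for Ccl2, 18.5 for Stx11, 17.6 for Vcam1, 11.7 for Cxcl2, 11.3 for Tlr2 and 10.9 for Tnfaip2.

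**Figure D1:**
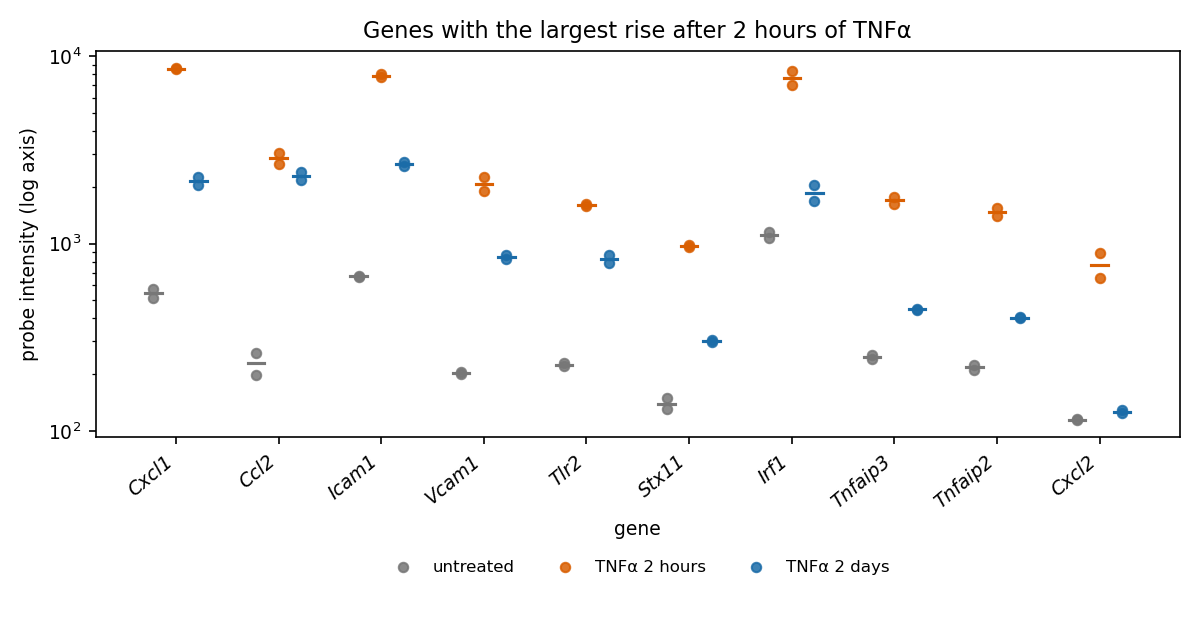
Probe intensity on a log axis for the 10 genes with the largest rise after 2 hours, by gene; each point is 1 array and each short line the mean of the 2 arrays of a group. Cxcl1 went from a mean of 544 in untreated cells to 8579 at 2 hours and stood at 2155 at 2 days, while Cxcl2 stood at 126 at 2 days against 115 in untreated cells.

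Falls at 2 hours were smaller. G6pc, the catalytic subunit of glucose-6-phosphatase, fell from 951 ± 205 to 287 ± 24.6 (n = 2 each), which is a log2 change of -1.72 (SE 0.14, adjusted p = 1.66e-09 by limma). The glucocorticoid-inducible genes Tsc22d3 and Sgk1 fell by 1.02 and 1.01 on the log2 scale, and Pik3r1, a regulatory subunit of phosphoinositide 3-kinase, fell by 0.98. The 2 other probes of Tsc22d3 gave -0.44, which was called, and 0.08, which was not. The other named falls were Mfsd2a (-0.87), the homeobox gene Hhex (-0.84), the Wnt receptor Fzd5 (-0.83), Dipk2a (-0.82), Iffo2 (-0.79) and Masp1 (-0.78), a protease of the lectin complement pathway. The 2 other probes of Masp1 gave -0.21 and -0.12 at 2 hours and were not called, and 1 of them was called at 2 days (-1.36) where the probe used gave -0.04. Masp1 and Tsc22d3 each have 1 other probe that was lower at 2 days than at 2 hours, where the probe given here was higher.

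In total 379 of 13438 genes were called at 2 hours, 237 higher and 142 lower, of which 52 and 3 changed at least 2-fold. Among all genes, the arrays of the 2 groups did not overlap for 40.4%, where chance gives 33.3%. Without replicate 1 of the 2 hour group 209 genes were called, 156 higher and 53 lower, without its replicate 2 187 were called, 139 higher and 48 lower, and without untreated replicate 1 87 were lower. After normexp 95 were called, 81 higher and 14 lower, with the calls of Dipk2a, Foxo1, Foxa2, Prox1, Gadd45g, Igfbp1, Cyp2b10, Psmb10, Tapbpl, Cd14, Crp and Cfb among those lost, and with the mean of a gene's probes 250 were called, without Masp1, Bcl2l11, Tapbpl, Cyp2b10 and Cfb. Of the genes named here, no other probe was called for Masp1, Iffo2, Junb, Foxo1, Nr5a2, Prox1, Bid, Bcl2l11, Tapbpl and Cyp2b10, and the other probes of Vcam1 (0.07 to 0.84), Nfkbia (0.59), Birc2 (0.84 to 1.11), Tnfaip2 (1.71 to 1.87) and Cxcl2 (2.06) changed less.

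Among the fixed lists, the NF-κB feedback and signalling genes had 14 of 24 tested members higher and 0 lower by limma, and 20 higher when adjusted over the list alone. Besides Tnfaip3 and Tnfaip2, these included the NF-κB inhibitor Nfkbia (2.43) and the anti-apoptotic ubiquitin ligase Birc2 (2.03). The list's adjusted p was 1.88e-55 by camera and adjusted p = 0.0118 with an estimated correlation. Of 21 chemokines, 10 were higher, or 11 adjusted over the list alone, with Ccl7 at 1.59, or 2.80 after normexp (camera adjusted p = 1.24e-23; adjusted p = 0.0247 with an estimated correlation). No member of either list had an unadjusted p under 0.05 in the lower direction. After normexp 12 and 8 members of these lists were higher.

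Smaller parts of 6 other lists rose, which made 8 lists called, and the calls of these 6 were lost with an estimated correlation. With fry the adhesion, cytokine and cell death lists kept their calls (fry adjusted p = 0.00433, 0.00478 and 0.0407). The antigen presentation, interferon response and positive acute phase lists lost theirs (fry adjusted p = 0.0664, 0.0971 and 0.152). Of 11 adhesion molecules 2 were higher, Icam1 and Vcam1, also 2 adjusted over the list alone (adjusted p = 0.104 with an estimated correlation). Of 24 cytokines, receptors and feedback genes 5 were higher, or 7 adjusted over the list alone, led by the cytokine signalling inhibitors Cish (1.76) and Socs2 (0.92), with adjusted p = 0.13 with an estimated correlation. Of 24 interferon response genes 6 were higher, or 8 adjusted over the list alone, with Gbp2 at 1.29 (adjusted p = 0.273 with an estimated correlation). Of 26 positive acute phase genes 4 were higher, or 7 adjusted over the list alone, led by the serum amyloid Saa3 (2.00), with adjusted p = 0.395 with an estimated correlation. The other 3, Cd14, Crp and Cfb, each lost their call without at least 1 array. Antigen presentation and immunoproteasome genes had 2 of 19 higher, Psmb10 (0.73) and Tapbpl (0.65), or 6 adjusted over the list alone, and cell death genes had 5 of 26 higher and 2 lower, or 6 and 2 adjusted over the list alone. For both of these lists adjusted p = 0.272 with an estimated correlation. The cell death genes that rose included the pro-apoptotic Bid (1.17), Bcl2l11 (0.77, or 1.36 after normexp) and the death receptor Fas (1.13). After normexp fewer members were higher: 3 cytokine, 2 interferon response, 1 positive acute phase and 3 cell death genes, while both adhesion molecules were kept and both antigen presentation calls and the 2 cell death falls were lost.

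No metabolic list was called at 2 hours. By limma 0 of 26 urea cycle and amino acid catabolism genes were called, against 1 at an unadjusted p under 0.05 (fry adjusted p = 0.76). Of 24 cytochrome P450 genes 1 was lower, Cyp2b10 (-0.44), also 1 adjusted over the list alone, a call lost without untreated replicate 1 (-0.46), untreated replicate 2 (-0.42) or replicate 2 of the 2 hour group (-0.29). Bile acid synthesis and transport had 2 of 25 higher and 2 lower, the same adjusted over the list alone, lipogenesis 2 of 24 higher and 1 lower, or 2 and 2, and cholesterol synthesis 1 of 17 higher, also 1; every call in these 3 lists was lost after normexp and also without at least 1 array. Of 24 fatty acid oxidation genes 0 were called by limma, with 5 at an unadjusted p under 0.05 (fry adjusted p = 0.922). Of 14 hepatocyte markers 0 were called, with 4 at an unadjusted p under 0.05 (fry adjusted p = 0.934). In the glucose list G6pc and the transcription factor Foxo1 (-0.75) were lower and Igfbp1 (0.53; 0.44 and not called without replicate 2 of the 2 hour group) was higher, of 22, or 2 lower and 2 higher adjusted over the list alone. Hepatocyte transcription factors moved both ways, with Nr5a2 at 0.90, Foxa2 at -0.74 and Prox1 at -0.61, of 22, or 4 lower and 1 higher adjusted over the list alone. Immediate early genes also did, with Junb (2.83-fold) and Egr1 (log2 1.20) among 5 higher and Gadd45g (-0.67) among 3 lower, of 20, or 5 and 4 adjusted over the list alone (camera adjusted p = 0.0509). The oxidative stress list had 3 of 25 higher, led by haem oxygenase 1, Hmox1 (1.53), and 1 lower, the same adjusted over the list alone. After normexp 1 glucose gene was lower, 1 transcription factor, 2 immediate early genes and 1 oxidative stress gene were higher, and the other calls in these lists were lost. Of 15 macrophage markers 0 were called by limma, with 2 at an unadjusted p under 0.05 (fry adjusted p = 0.591). Complement and coagulation had 1 of 29 lower, Masp1, endoplasmic reticulum stress 1 of 22 higher and 2 lower, stellate cell markers 1 of 14 higher and bile duct markers 1 of 10 higher, Sox9 (0.79); adjusted over the list alone these were 2 lower, 1 and 2, 2 higher and 1 higher. After normexp the endoplasmic reticulum stress and stellate cell calls were lost. The calls of Calr, Herpud1 and Reln in these 2 lists, and of Isg15, Rsad2, Ifngr1, Gclc and Mt2 in lists above, were also lost without at least 1 array. In the other 6 lists 0 members were called by limma, with 0 or 1 each at an unadjusted p under 0.05 (fry adjusted p from 0.0407 to 0.923). By fry, though not by camera, the cell cycle and endoplasmic reticulum stress lists were called lower (fry adjusted p = 0.0407 each). The median, mean and test differed in sign for 5 lists that were not called at 2 hours (complement and coagulation, fatty acid oxidation, lipogenesis, macrophage and endothelial), for 0 lists at 2 days, and for 3 that were not called between the times (endoplasmic reticulum stress, ribosomal, and lymphocyte and neutrophil).

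The second comparison asked what a 2 day exposure did. Cyp2b10, a drug-metabolising cytochrome P450, fell from 7848 ± 156 to 895.9 ± 23.3 (n = 2 each), a log2 change of -3.13 (SE 0.11, adjusted p = 2.54e-16 by limma). Cps1, the first enzyme of the urea cycle, fell by 3.10 on the log2 scale, and Arg1, its last enzyme, by 2.84. Other cytochrome P450 genes, Cyp3a11 (-2.97), Cyp2a12 (-2.96), Cyp2b23 (-2.96, but -0.14 and not called on its other probe) and the steroidogenic Cyp17a1 (-2.81) fell by similar amounts. Rdh7, a retinol dehydrogenase (-2.59), Gnmt, the liver's glycine N-methyltransferase (-2.43), and Uox, urate oxidase (-2.05), completed the 10 largest falls.

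**Figure D2:**
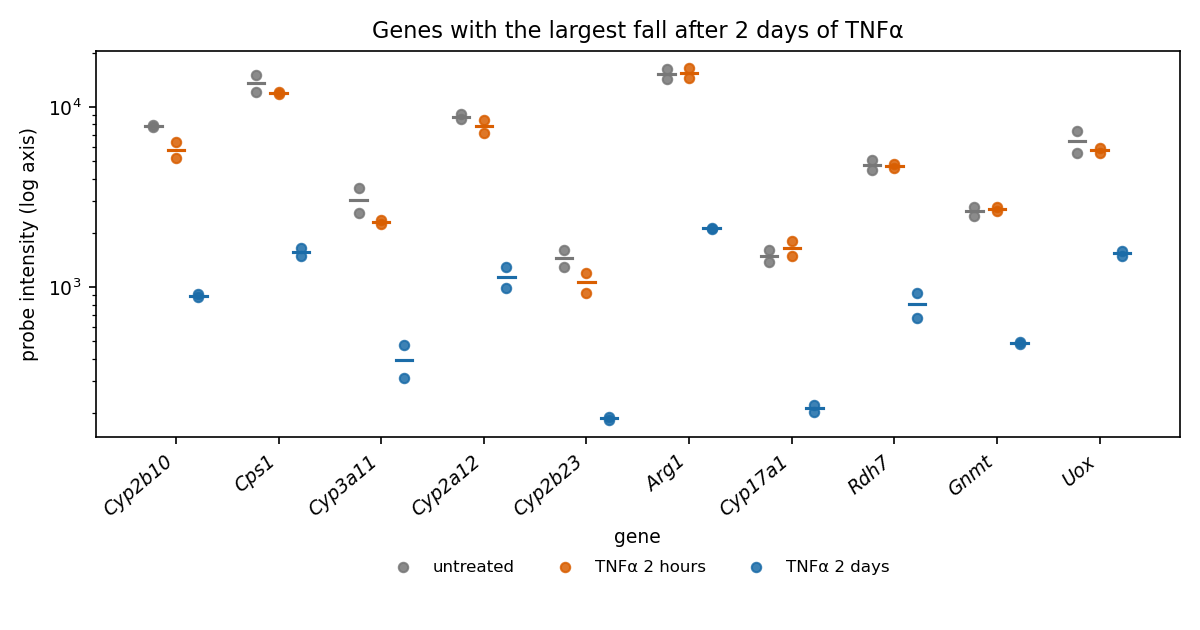
Probe intensity on a log axis for the 10 genes with the largest fall after 2 days, by gene; each point is 1 array and each short line the mean of the 2 arrays of a group. Arg1 had means of 15200 in untreated cells, 15470 at 2 hours and 2119 at 2 days.

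The largest rise at 2 days was that of Ccl2, from 229.7 ± 44.1 to 2293 ± 152 (n = 2 each), a 10.1-fold change (log2 3.33, SE 0.12, adjusted p = 2.54e-16 by limma). Ubd, a ubiquitin-like protein inducible by inflammatory cytokines, rose 9.3-fold, and Saa3, an acute phase serum amyloid, 4.93-fold. The guanylin genes Guca2b and Guca2a rose 4.27-fold and 3.51-fold, with wide spread between the 2 day arrays (557 ± 276 and 574.4 ± 214, n = 2 each). Vcam1 rose 4.15-fold, Icam1 3.99-fold, Cxcl1 3.96-fold, Tlr2 3.67-fold and the chemokine Cxcl16 3.48-fold. After normexp Ccl2 rose 16.3-fold, Guca2b 13.7-fold, Guca2a 6.91-fold and Vcam1 6.71-fold, and the log2 changes of Cyp2b23 and Cyp17a1 were -3.83 and -3.53.

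In total 1701 of 13438 genes were called at 2 days, 906 higher and 795 lower, of which 80 and 89 changed at least 2-fold. Among all genes, the arrays of the 2 groups did not overlap for 49.6%, where chance gives 33.3%. After normexp 654 genes were called, 348 higher and 306 lower, without Hamp, Mlkl, Herpud1, Hprt, Tfrc, Pgk1, Acta2, Krt23, C1qc, Oit3 and Stab2, and without replicate 2 of the 2 day group 600 were higher. Of the genes named here, no other probe was called for Cyp2b23, Hgd, Acot1, Nfkbia, Oasl2, Bid, Mlkl, Cdk4, Reln, Il18, Junb, Tfrc, Pgk1 and Oit3. The other probes of Cyp2b10 (-0.60), Vcam1 (0.05 to 0.50), Cxcl16 (0.78), Cd44 (0.04 to 0.91), Psmb8 (0.58), Slc2a2 (-0.65 to -0.53) and Slc7a11 (-0.16 to 0.92) changed less, and that of Arg1 (-3.47) more. No untreated array is labelled with a time in culture, so exposure and time in culture are not separated in this comparison.

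Urea cycle and amino acid catabolism genes fell most widely, with 20 of 26 tested lower and 0 higher by limma, or 21 lower adjusted over the list alone. Besides Cps1, Arg1 and Gnmt, the tyrosine-degrading Hgd fell by 1.88 on the log2 scale (camera adjusted p = 1.85e-30; adjusted p = 0.0752 with an estimated correlation). No member had an unadjusted p under 0.05 in the higher direction. Of the 30 lists, 21 were called at 2 days with the preset correlation, 22 with fry and 0 with an estimated correlation. Fry did not call the bile acid (fry adjusted p = 0.0775) and complement and coagulation lists (fry adjusted p = 0.0945), which camera called. It called the endoplasmic reticulum stress list lower and the ribosomal and stellate cell lists higher, which camera did not call. Of 24 cytochrome P450 genes 15 were lower and 1 higher, or 16 and 1 adjusted over the list alone, with Cyp2a5 at -2.00 on the probe used and -0.53 to -0.13 on its 4 others (adjusted p = 0.0752 with an estimated correlation). Of 22 glucose metabolism genes 10 were lower and 1 higher, the same numbers adjusted over the list alone, among them G6pc (-1.73), Ugp2 (-1.33) and the glucose transporter Slc2a2 (-1.28), with adjusted p = 0.0752 with an estimated correlation. Bile acid synthesis and transport had 11 of 25 lower and 2 higher, or 11 and 3 adjusted over the list alone. The bile acid conjugating enzymes Baat and Slc27a5 both fell by 1.37 on the log2 scale and the exporter Abcc4 rose (1.03, or 1.73 after normexp), with adjusted p = 0.247 with an estimated correlation. After normexp 15 urea cycle, 13 P450, 8 glucose and 7 bile acid genes were lower, and 1 glucose and 2 bile acid genes were higher.

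Of 20 negative acute phase and plasma transport genes 7 were lower, or 9 adjusted over the list alone, including Apoh (-1.12), Igf1 (-1.11) and Apoc3 (-0.90), with adjusted p = 0.0752 with an estimated correlation. Of 29 complement and coagulation genes 11 were lower and 3 higher, or 12 and 4 adjusted over the list alone, with coagulation factors F10 (-1.36) and F12 (-1.12) lowest (adjusted p = 0.358 with an estimated correlation). Positive acute phase genes split, with 4 of 26 higher, among them Saa3 (2.30), Cd14 (1.06) and the iron hormone Hamp (1.06), and 9 lower, among them the fibrinogen chain Fga (-0.90). Adjusted over the list alone 5 were higher and 10 lower, and the list was not called (camera adjusted p = 0.187). Hepatocyte markers had 7 of 14 lower, or 9 adjusted over the list alone, including the asialoglycoprotein receptor Asgr1 (-1.60), with adjusted p = 0.0752 with an estimated correlation. Apart from Asgr1 and Asgr2, every gene of this list also stands in another fixed list, such as Cps1 and Cyp3a11. Its result is therefore not separate from those of the other lists. Of 22 hepatocyte transcription factors 9 were lower, or 11 adjusted over the list alone with 1 higher, including the nuclear receptors Nr1i2 (-0.91) and Hnf4a (-0.82), with adjusted p = 0.0752 with an estimated correlation. After normexp 4 negative acute phase, 3 complement, 7 positive acute phase, 5 hepatocyte marker and 2 transcription factor genes were lower, and 1 complement and 2 positive acute phase genes were higher. The probes of Alb and Fgb, named after their values were seen, lay near the array median in untreated cells (159.8 and 132.8) and so measured little.

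Of 17 cholesterol synthesis and uptake genes 5 were lower, or 7 adjusted over the list alone, with Ebp and Sqle both at -0.80. Of 24 lipogenesis and triglyceride genes 7 were lower and 1 higher, or 8 and 1 adjusted over the list alone, with the phosphatidate phosphatase Lpin1 at -0.97. For both lists adjusted p = 0.0752 with an estimated correlation. Fatty acid oxidation and ketogenesis had 4 of 24 higher and 3 lower, or 4 and 6 adjusted over the list alone, with Acot1 at 0.60 (camera adjusted p = 0.651). The 3 other rises, Acaa1b, Bdh1 and Acads, each lost their call without at least 1 array. After normexp 4 cholesterol and 2 lipogenesis genes were lower, 1 fatty acid oxidation gene was higher, and the other calls in these lists were lost.

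Antigen presentation and immunoproteasome genes had 13 of 19 higher and 0 lower by limma, or 16 higher adjusted over the list alone, including the immunoproteasome subunits Psmb10 (1.39) and Psmb8 (1.35), the peptide-loading Tapbp (0.99) and the class I heavy chain H2-K1 (0.80). Interferon response genes had 14 of 24 higher and 0 lower, or 16 higher adjusted over the list alone, including Gbp2 (1.54), Oasl2 (1.46, or 2.50 after normexp, and -0.07 to 0.15 on its 2 other probes, not called) and Isg15 (1.29). NF-κB feedback and signalling genes had 12 of 24 higher, the same number adjusted over the list alone, with Nfkbia (1.32) and Tnip1 (1.28), and chemokines 6 of 21, also 6 adjusted over the list alone. Adhesion molecules had 4 of 11 higher and 1 lower, the same adjusted over the list alone, with Cd44 (1.68) beside Vcam1 and Icam1. For each of these 5 lists adjusted p = 0.0752 with an estimated correlation. At an unadjusted p under 0.05, 0 interferon response, antigen presentation and NF-κB genes were lower. Of 15 macrophage markers 6 were higher, or 7 adjusted over the list alone, with the complement component C1qb (0.75), Laptm5 (0.61) and Fcer1g (0.56) (adjusted p = 0.0834 with an estimated correlation). Their untreated intensities were 177.2, 220.2 and 190.4, close to the array median. After normexp 6 antigen presentation, 9 interferon response, 9 NF-κB, 5 chemokine, 3 adhesion and 4 macrophage genes were higher.

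**Figure D3:**
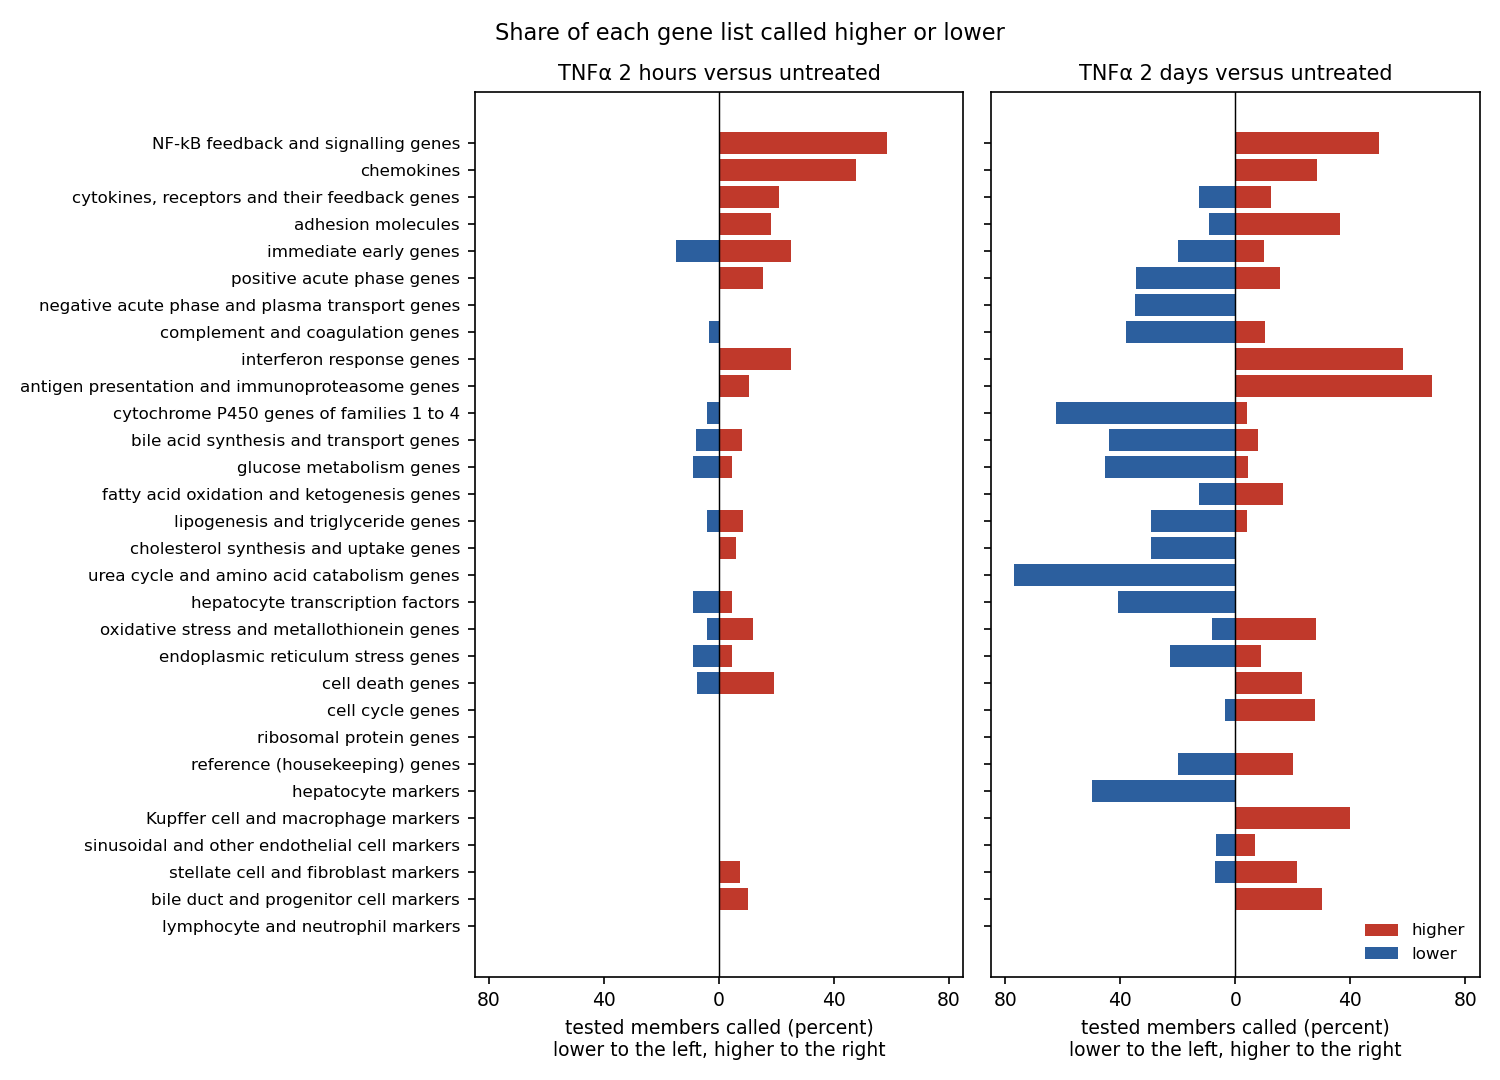
Percent of the tested members of each of the 30 fixed lists called higher (bars to the right) or lower (bars to the left) after 2 hours and after 2 days against untreated cells. At 2 hours the longest bar is that of the NF-κB feedback and signalling genes (14 of 24 higher), and at 2 days that of the urea cycle and amino acid catabolism genes (20 of 26 lower).

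Other lists changed in smaller numbers at 2 days. Of 29 cell cycle genes 8 were higher and 1 lower, or 12 and 1 adjusted over the list alone, including the replication factor Mcm4 (0.74), Cdk4 (0.67) and Ccnd1 (0.55). Of 26 cell death genes 6 were higher, or 9 adjusted over the list alone, including Apaf1 (1.05), Bid (0.89) and the necroptosis effector Mlkl (0.57). Of 25 oxidative stress and metallothionein genes 7 were higher and 2 lower, the same adjusted over the list alone, with the cystine transporter Slc7a11 (1.54) and Gsta4 (1.15) higher and the metallothionein Mt2 (-1.16) lower. Bile duct and progenitor markers had 3 of 10 higher, also 3 adjusted over the list alone: Sox9 (1.78), Cldn4 (0.95) and Krt23 (0.52; 0.38 and not called without replicate 2 of the 2 day group). For these 4 lists adjusted p = 0.0752 with an estimated correlation. Immediate early genes had 4 of 20 lower, led by Atf3 (-0.92) and Zfp36 (-0.83), and 2 higher, or 6 and 2 adjusted over the list alone (adjusted p = 0.0834 with an estimated correlation). This list's call was also lost without untreated replicate 2 (camera adjusted p = 0.0526). After normexp 4 cell cycle, 3 cell death, 3 oxidative stress and 2 bile duct genes were higher, and 2 oxidative stress and 2 immediate early genes were lower.

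Of 24 cytokines, receptors and feedback genes 3 were higher and 3 lower, or 5 and 3 adjusted over the list alone, with Socs2 at 0.85. Of 22 endoplasmic reticulum stress genes 2 were higher and 5 lower, or 3 and 6 adjusted over the list alone, with Herpud1 at -0.64. Stellate cell and fibroblast markers had 3 of 14 higher, with Timp1 (0.87) and Vim (0.83), and Reln (-0.82) lower, the same numbers adjusted over the list alone. Endothelial markers had 1 of 15 higher and 1 lower, also 1 and 1 adjusted over the list alone. Of 10 reference genes 2 were higher, with Gusb at 0.69, and 2 lower, with Hprt at -0.55, or 3 and 2 adjusted over the list alone. The calls of Il18, Acta2, Oit3, Stab2, Tfrc and Pgk1 in these lists, and of Junb, Rbp4 and C1qc in lists above, were each lost without at least 1 array. By camera none of these lists was called (camera adjusted p from 0.187 to 0.827). Fry called the endoplasmic reticulum stress list lower (fry adjusted p = 0.0146) and the stellate cell list higher (fry adjusted p = 0.0478). After normexp 1 cytokine, 2 stellate cell and 1 reference gene were higher, 1 cytokine and 1 stellate cell gene were lower, and every endoplasmic reticulum stress and endothelial call was lost. By limma 0 of 22 ribosomal protein genes were called, with 1 at an unadjusted p under 0.05 (fry adjusted p = 0.0315), and 0 of 6 lymphocyte and neutrophil markers, with 0 at an unadjusted p under 0.05 (fry adjusted p = 0.333).

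The third comparison set 2 days against 2 hours, which also tests whether the 2 changes against untreated cells differ. The cells of these groups may also have differed in time in culture, which is not separated from exposure here either. Without background correction Ubd had the largest rise, from 359 ± 41.2 to 2512 ± 553 (n = 2 each; log2 2.79, SE 0.13, adjusted p = 1.82e-14 by limma), followed by Guca2b (1.98), Guca2a (1.68), the orphan receptor Gpr176 (1.58) and Igfbp7 (1.56). Cyp17a1 (-2.94), Cps1 (-2.92), Arg1 (-2.87), Cyp2a12 (-2.79) and Cyp2b10 (-2.69) had the largest falls. In all 2056 genes differed, 1160 higher and 896 lower at 2 days, of which 54 and 128 changed at least 2-fold. Among all genes, the arrays of the 2 groups did not overlap for 52.8%, where chance gives 33.3%. Without replicate 2 of the 2 hour group 1270 differed, 676 higher and 594 lower, and the number higher was 743 without its replicate 1 and 736 without replicate 2 of the 2 day group. After normexp 810 differed, 413 higher and 397 lower, and Guca2b (3.38) rose more than Ubd (3.17), with Gpr176 at 2.70, Guca2a at 2.49 and Cyp17a1 at -3.67.

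Between the times, 15 of 24 NF-κB feedback and signalling genes were lower at 2 days and 1 was higher, the same adjusted over the list alone (adjusted p = 0.0927 with an estimated correlation). Interferon response genes had 11 of 24 higher and 1 lower, or 14 and 1 adjusted over the list alone (adjusted p = 0.275 with an estimated correlation). Antigen presentation genes had 10 of 19 higher, or 13 and 1 lower adjusted over the list alone (adjusted p = 0.0927 with an estimated correlation). After normexp 9 NF-κB genes were lower, 5 interferon response and 5 antigen presentation genes were higher, and 1 interferon response gene was lower. Of the 237 genes higher at 2 hours, 152 were lower at 2 days than at 2 hours, 91 were still called higher than in untreated cells at 2 days and 127 were not called there. Of the 142 genes lower at 2 hours, 57 were also lower at 2 days and 76 were not called. A further 806 genes were higher and 719 lower at 2 days without a call at 2 hours, of which 616 and 501 also differed between the times in that direction.

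**Figure D4:**
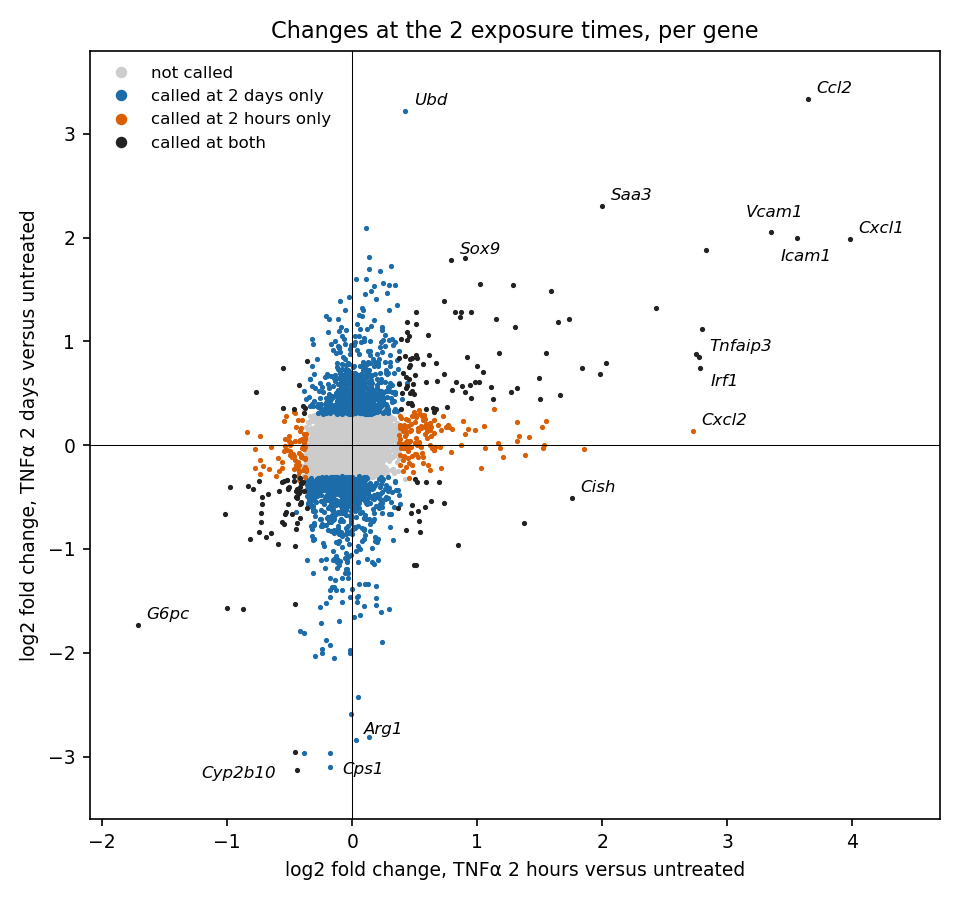
Log2 fold change against untreated cells after 2 hours (horizontal axis) and after 2 days (vertical axis), 1 point per gene, coloured by where the gene was called. Cxcl2 changed by 2.73 at 2 hours and 0.14 at 2 days, and Cps1 by -0.18 and -3.10.

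Across genes, which are not independent replicates, the changes at the 2 times correlated at r = 0.31 and rho = 0.269. Unchanged groups set against the same 2 untreated arrays gave r = 0.501 and rho = 0.484 in simulation, above the observed values. The simulated values come from the shared arrays alone, and the observed ones also hold changes seen at 1 time only. The gap therefore does not show that the 2 responses agree less than unchanged groups would. The covariance was 0.0166 against 0.00557 simulated, a difference of 0.0111. The 91 genes higher at both times compare with 0.02 in simulation and 16 for independent lists, and the 57 lower at both with 0 and 8.4. The simulated overlaps set no scale for these counts, because unchanged groups had a mean of 0.13 and 0.11 calls at the 2 times. The 2 comparisons were not set against separate untreated arrays, so part of the overlap may come from the shared arrays. The number lower at both times was 36 without untreated replicate 1, and 29 and 24 without replicates 1 and 2 of the 2 hour group.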

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

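The tests of a lower hepatocyte share, of scaling and of time in culture were chosen only after the result was seen, and for the first 2 of these a second test, and for scaling 1 more, was added after the earlier ones had left the explanation open.

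The change against untreated cells differed between 2 days and 2 hours for 2056 genes and for 20 of the 30 lists (camera with the preset correlation; 0 lists with an estimated correlation, where 13 had an unadjusted p under 0.05). Of these genes, 28 were called in opposite directions at the 2 times. Among members of the fixed lists, the difference of 2 days minus 2 hours was -2.27 for Cish, -1.65 for Mt2, -1.37 for Zfp36, -1.26 for Igfbp1, -1.25 for Reln, -1.18 for Cidec (-1.96 after normexp), -1.16 for Abcg5, -1.12 for Dgat2 and -0.95 for Crp, all higher at 2 hours and lower at 2 days than in untreated cells. The 2 hour calls of 7 of these 9 were each lost without at least 1 array, that of Cish was not, and that of Zfp36 was not refitted that way. Without replicate 2 of the 2 hour group, Abcg5 (0.44), Crp (0.44), Igfbp1 (0.44), Reln (0.43), Dgat2 (0.48) and Mt2 (0.33) were not called, nor without untreated replicate 2 were Abcg5 (0.40), Crp (0.46), Reln (0.40), Dgat2 (0.30) and Mt2 (0.31). Without replicate 1 of the 2 hour group Cidec (0.53), Dgat2 (0.46) and Reln (0.43) were not called, nor without untreated replicate 1 were Cidec (0.49) and Reln (0.46). Cish, an inhibitor of cytokine receptor signalling, rose by 1.76 at 2 hours and fell by 0.51 on the log2 scale at 2 days. After normexp none of the 9 kept both calls: the 2 hour calls of the 8 other than Cish were lost, that of Zfp36 with an adjusted p = 0.268, and so were the 2 day calls of Cish (-0.56, adjusted p = 0.0625), Dgat2 (adjusted p = 0.0875) and Crp (adjusted p = 0.3).

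Probes without a single gene symbol entered only the setting that tested every probe on its own. There 30 of 4847 were called at 2 hours and 296 at 2 days, or 0.619% and 6.11%, against 2.18% and 10.4% of named probes.

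For the fall of hepatocyte genes at 2 days, 3 explanations were weighed: under the first test of a lower share of hepatocyte RNA as the whole cause, 29.2% of 48 measurable hepatocyte genes (95% exact binomial interval 17 to 44.1) lay above -0.3, which spans the limit of 20% set for that test; the second found an SD of their changes 9.26 times the median SE (0.991 against 0.107), with 34 lower and 3 higher, which argues against an equal fall of all of them. A lower share stays open as part of the cause, and the rises of 6 of 15 macrophage and 3 of 10 bile duct markers go with it. The other 3 lists of non-hepatocyte markers were not called at 2 days. Of these, endothelial markers had 1 of 15 higher and 1 lower, and stellate cell markers 3 of 14 higher and 1 lower. Lymphocyte and neutrophil markers had 0 of 6 called. Of the urea cycle and P450 genes called lower, 35 in number, 80% were still called under the first test of scaling. Normexp ended the other 7 calls, for a reason that was not tested (median -0.57, SE 0.11 before, and -0.70, SE 0.16 after). Under the second test, without normexp, 100% were still called, but its settings moved few calls of any kind. Of all 2 day calls cyclic loess kept 95.6%, the offset 98.8%, median centring 99.8% and repeated quantile normalization 100%. The second test therefore could not decide. The last test of scaling set all 50 tested urea cycle and P450 genes against 100 genes of like untreated intensity each. A rescaling that keeps the order of genes within an array would move both alike. The median difference was -0.655 (95% bootstrap interval -1.08 to -0.421, genes taken as independent). Such a rescaling alone would not make this fall relative to those neighbours. The shared distribution tends to hold the neighbours near 0, and their median was 0.00443. The test therefore cannot tell a fall of these genes from a rise of most others that normalization removed. Longer time in culture cannot be told apart from 2 days of TNFα, because 0 untreated arrays are labelled with a time in culture, and it may account for part or all of the fall.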

How the results depend on the processing

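The normexp background correction was chosen after seeing the data; all other alternatives were fixed before. No called result changed direction when the same probe was followed, but between the times 1 other probe each of Tsc22d3 and Masp1 was called the other way. Of 38, 73 and 78 named called genes with other tested probes at 2 hours, at 2 days and between the times, 19, 27 and 31 had none of those called. Among them were Junb (-0.10 on the other probe) and Foxo1 (0.00) at 2 hours, and Cyp2b23 (-0.14) at 2 days. Counts are total, higher and lower genes for 2 hours against untreated, 2 days against untreated, and 2 days against 2 hours. With normexp they were 95, 81 and 14; 654, 348 and 306; and 810, 413 and 397, and 23.7%, 37.3% and 37.7% of the main calls were kept; 85.3% of the 2 hour calls were higher, against 62.5%. At least 2-fold gave 55, 52 and 3; 169, 80 and 89; and 182, 54 and 128, because the rule removes smaller changes. The mean of a gene's probes gave 250 at 2 hours with 79 lower, an adjusted p under 0.1 gave 217 lower at 2 hours, and every probe on its own gave 1226 lower at 2 days and 1443 between the times, since more probes than genes were tested. Leaving out 1 array at a time, where a lone array is assumed to vary like the other groups, gave 187 to 384, 139 to 243 and 48 to 141 at 2 hours; 1150 to 1536, 600 to 813 and 541 to 723 at 2 days; and 1270 to 2155, 676 to 1212 and 594 to 943 between the times. Lists called numbered 2, 0 and 0 with an estimated correlation, and 8 to 13, 21 and 19 to 21 over the left-out arrays. The correlation of the changes was 0.319 without a filter and 0.276 to 0.413 over the left-out arrays, with 61 to 86 genes higher and 24 to 53 lower at both times. With fry 7, 22 and 19 lists were called in the 3 comparisons, not all of them lists that camera called. Except where stated, the cause was not tested. Median centring, cyclic loess, repeated quantile normalization, the offset, the filters, the variance models and the fit of 2 groups kept every count within 1.5 times.

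With the replicate number as a block, 363, 1638 and 2007 genes were called. Same-numbered arrays did not deviate together (correlations -0.148, -0.0753 and 0.0364), so no pairing was seen, though a shared origin cannot be excluded. Signal over background limits dim genes: for 6 of the 20 genes named at each time, normexp moved the fold by over 1.5 times.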

Other observations

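The tests of gene families named by their symbols, the genes named from them and the count of glucocorticoid-inducible genes at 2 days were chosen only after the result was seen; the tests of the glucocorticoid, FOXO and YAP lists were written before their values were seen, after the falls and rises they address had been noticed.

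Protein families were also grouped by their symbols, and some of their members stand in the fixed lists as well: 5 of 14 apolipoproteins, 1 of 15 UDP glucuronosyltransferases, 6 of 20 glutathione S-transferases, 2 of 13 claudins and 3 of 26 keratins. Of the apolipoproteins, the protein parts of plasma lipoproteins, 9 were lower at 2 days, 6 of them outside the lists, with Apoa4 at -1.97 and Apoc4 at -1.28 (camera adjusted p = 8.5e-14; adjusted p = 0.25 with an estimated correlation). Of the UDP glucuronosyltransferases 4 were lower, with Ugt1a1, which conjugates bilirubin, at -0.91 (camera adjusted p = 0.012; adjusted p = 0.32 with an estimated correlation), and the sulfotransferases Sult1a1 (-2.00) and Sult1d1 (-1.96) were lower while Sult1c2 (0.42) was higher, of 8 (camera adjusted p = 0.017; adjusted p = 0.35 with an estimated correlation). Galectins Lgals1 (1.25) and Lgals3 (0.89) were higher, of 7 (adjusted p = 0.32 with an estimated correlation), and so were 4 of 8 aldo-keto reductases of family 1, led by Akr1b10 (0.90; adjusted p = 0.35 with an estimated correlation). The proteasome subunits Psmd10 (1.01) and Psma7 (0.43) were higher, of 31 outside the immunoproteasome (adjusted p = 0.31 with an estimated correlation). In all, 6 of the 12 families tested were called at 2 days and 0 at 2 hours with the preset correlation, and 0 with an estimated one at either time.

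Families that were not called at 2 days held single genes with large changes. Among 26 keratins Krt17 rose by 1.72, and among 15 tubulins Tubb2b (0.98), Tuba1a (0.90) and Tubb5 (0.62) rose. Of 20 glutathione S-transferases 7 were higher and 3 lower, 4 and 3 outside the lists (camera adjusted p = 0.062). Claudins had Cldn4 higher (0.95) and Cldn1 (-0.56), Cldn14 and Cldn2 lower, of 13.

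Sgk1 and Tsc22d3, which glucocorticoids induce, fell at 2 hours although the medium held dexamethasone. The tests that follow used only list members with an untreated mean log2 of at least 8. These were 11 of 20 glucocorticoid, 10 of 19 FOXO and 10 of 21 YAP genes. If glucocorticoid receptor activity had fallen, other inducible genes could have fallen too, but 11 of them had a median change of 0.008 (95% bootstrap interval -0.2 to 0.17), with 2 higher and 1 lower, which leaves the explanation open. More insulin signalling, as after a change to fresh medium, was tested on 10 genes that FOXO factors induce, with a median of -0.024 (-0.22 to 0.07), which leaves it open too. At 2 days 7 of the same 11 glucocorticoid-inducible genes were lower and 1 higher, with Fkbp5 at -1.39 and Per1 at -0.70.

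Sox9, Krt17 and Cd44 rose at 2 days, by 1.78, 1.72 and 1.68. A candidate explanation, more YAP/TEAD activity, was tested on 10 other target genes, whose median was -0.0074 (95% bootstrap interval -0.27 to 0.44), with 4 higher and 2 lower, so the test did not decide. No other explanation was tested for this rise, and time in culture is not separated from exposure for it.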
